A study of Mus musculus with 12 samples.

How the data were processed

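Whole-kidney RNA of 3-week-old mice was measured on 12 Affymetrix mouse whole-transcript arrays, per the labels, in 4 groups of 3 arrays: Pparg null, mixed C57BL6/SV129 controls, A-ZIP and FVB controls. Each array held a pool of RNA from 3 mice, so n is 3 pools per group. The deposited log2 values had been made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes, which corrects background, normalizes across arrays and gives 1 value per probe set. Versions, settings and the genome build of the array annotation are not given in the sources used here. Values were used as deposited. Array medians over all probe sets lay between 7.17 and 7.21, and arrays of a group correlated at a mean r of 0.996 to 0.998 across the genes tested.

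Of 35556 probe sets 21789 had 1 gene symbol, 1621 had several and 12146 had none in the platform table. Symbols were updated by Entrez number for 21698 probe sets from a mouse RefSeq gene table, and 91 kept the platform's symbol. For 999 genes with more than 1 probe set the one with the highest mean was used, which left 19938 genes. Probe sets with no single symbol were tested only in an alternative.

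Group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (8 residual degrees of freedom, 3.71 from the prior). The contrasts were Pparg null minus mixed control, A-ZIP minus FVB control, and the difference of these 2 effects. P-values were adjusted by Benjamini and Hochberg over the genes tested, and an adjusted p under 0.05 was the threshold. The median SE of a difference was 0.0698 in log2. Adjusting over the list alone repeated the correction within 1 list. Gene lists were tested with camera at a preset correlation of 0.01 over 43 of 44 lists, those with at least 3 measured genes, and again with an estimated correlation and with fry. The lists held 923 entries, of which 841 were measured. They covered metabolism, matrix, nephron segments, immune cells, hormones, clock, handling, sex, and tissues that may lie beside the kidney. Overlap between comparisons was set against n1 × n2 / N per direction with Fisher's exact test.

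The lists, contrasts, alternatives and the rule for naming genes were written before the data were examined. The rule named Pparg, then for each comparison the 12 largest rises and 12 largest falls past the threshold with no overlap between groups, leaving out predicted genes. It added up to 4 members with the smallest p of each list past the threshold (3 for lists of other tissues, sex, time and handling), up to 10 genes of the third contrast, and the 10 shared genes with the largest smaller change. The text prints part of the list members it names. Genes named outside it are marked as chosen after their values were seen.

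Alternatives were quantile normalization again, a shift to equal medians, leaving out genes under percentile 25 or 50 of mean expression, the mean of a gene's probe sets, all probe sets, only the groups compared, a variance trend, robust variance, array weights, the replicate number as a block, each array left out, an adjusted p under 0.10, and a fold of at least 1.5. On simulated data with 50 changed genes per size, the Pparg null contrast found 36% at a log2 change of 0.3, 80% at 0.5, 100% at 1 and 100% at 1.5, with 9 calls among 19738 unchanged genes and 0 in the A-ZIP contrast. A list moved by 0.2 was called, as 1 of 1 lists called. The simulated noise was independent between genes, whereas the correlation estimated in the data reached 0.784 for the cell cycle list. The simulation therefore does not check the list calls, or the number of false calls, where genes vary together. For the closing section 3 further lists (basal urothelium, superficial urothelium, smooth muscle) were written before the values of their genes were looked at. Scanner files were not used here.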

Results

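Gene expression was measured in whole kidneys of 3-week-old mice with 2 genetic changes that deprive the body of fat. Pparg null mice lack PPARγ, the nuclear receptor that drives the formation of fat cells, and are on a mixed C57BL6/SV129 background. A-ZIP mice carry a transgene that blocks the development of fat tissue and leaves Pparg in place, and are on the FVB background. Each line was set against controls of its own background, so the 2 differences share no array. The variance of each gene was fitted over all arrays, so the calls of the 2 comparisons are not independent. The 4 groups held 3 arrays each, and every array was hybridised with a pool of RNA from 3 mice, 36 mice in all. The first principal component (42.8% of the variance) set the strain backgrounds apart and the second (19.3%) set both mutants apart from their controls. Differences below are on the log2 scale, mutant minus control, with the SE from limma and n = 3 arrays per group. Because the arrays hold pools, the spread between them is smaller than that between single mice.

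Pparg itself was read first, on each array. In the Pparg null kidneys its probe set read 8.0, 8.20 and 8.01, against 7.90, 7.97 and 8.02 in the mixed controls, a difference of 0.11 ± 0.06 (limma adjusted p = 0.339). The A-ZIP arrays read 8.23, 8.17 and 8.16 and the FVB arrays 7.96, 7.94 and 8.0, a difference of 0.22 ± 0.06 (limma adjusted p = 0.0736). The probe set summarises probes along the transcript, and which part of the gene is missing in the null mice is not given in the sources used here. Its level therefore does not check the genotype, and the group names rest on the labels.

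The first comparison asked how the kidney transcriptome differs when Pparg is missing. Pparg null kidneys had 1055 of 19938 genes past the threshold, 532 higher and 523 lower than in mixed controls. The largest rises were in Igfbp1, a secreted IGF-binding protein that insulin represses (1.99 ± 0.29, 3.96-fold), Lcn2, the lipocalin NGAL used as a marker of tubular damage (1.94 ± 0.24), and Krt5, a keratin of basal epithelial cells (1.80 ± 0.14). Arntl, which encodes the clock protein Bmal1, rose by 1.62 ± 0.11, and Ddit4, an inhibitor of mTOR signalling, by 1.45 ± 0.21. The largest falls were in the glucuronosyltransferase Ugt2b38 (-1.65 ± 0.40), in Pdk4, the kinase that holds back pyruvate oxidation (-1.5 ± 0.23), in complement factor I, Cfi (-1.48 ± 0.14), and in Dnase1 (-1.30 ± 0.16). Ugt2b38 lost the threshold without Pparg null 2 or 3 or mixed control 1 or 3 (limma adjusted p up to 0.126), and the other 8 genes kept it with each of the 6 arrays left out.

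Other genes among the 12 with the largest rise were the clock-linked repressor Nfil3 (1.37), the retinoic acid binding protein Crabp1 (1.32), Ms4a4a (1.31), the ductal keratin Krt19 (1.25), Arhgef37 (1.21), the hypoxia-inducible factor subunit Hif3a (1.18) and Timd2 (1.17). The remaining large falls were in the thyroxine deiodinase Dio1 (-1.27), the clock output factor Dbp (-1.24), the organic anion transporter Slc22a7 (-1.18), Cyp2e1 (-1.14), the epoxygenase Cyp2c23 (-1.13), Ugt2b37 (-1.08), the Fc receptor Fcamr (-1.05) and the acyl-CoA thioesterase Acot3 (-1.02). Among these 24 genes Ugt2b38 had the highest adjusted p, 0.0378 by limma. The rule took them only from genes with no overlap between the 3 mutant and the 3 control arrays. Crabp1 lost the threshold without Pparg null 2 or 3 or mixed control 1, 2 or 3 (limma adjusted p up to 0.0893). Slc22a7 lost it without Pparg null 1, 2 or 3 or mixed control 1 or 2 (limma adjusted p up to 0.123) and Ugt2b37 without Pparg null 2 or 3 or mixed control 1 (limma adjusted p up to 0.0714).

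Most changes in the Pparg null kidney were small, with a median size of 0.354 among the 1055 genes, of which 181 changed by at least 1.5-fold and 38 by at least 2-fold. Groups did not overlap at all in 26.1% of all genes, against 10% by chance. With every array shifted to the same median the count was 1130, with another balance of 436 higher and 694 lower. The count was 330 without mixed control 1, 463 without mixed control 2, 627 without mixed control 3, 482 without Pparg null 2 and 487 without Pparg null 3. It was 607 with only these 2 groups in the model.

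Genes of fatty acid use were lower in the Pparg null kidney. Of 26 measured targets of PPARα, the receptor that drives fatty acid oxidation, 16 fell and 0 rose, 0 higher and 22 lower adjusted over the list alone, with a median of -0.47 (camera adjusted p = 2.58e-17 and adjusted p = 0.165 with an estimated correlation). Beside Pdk4 and Acot3, Plin2, a coat protein of lipid droplets (-0.84 ± 0.11), Plin5 (-0.54 ± 0.07) and Acot4 (-0.54 ± 0.06) fell. Among 21 mitochondrial fatty acid oxidation enzymes 4 fell, 0 higher and 14 lower adjusted over the list alone, the firmest of them Cpt2 (-0.44 ± 0.07), and the list was lower (camera adjusted p = 2.78e-07 and adjusted p = 0.202 with an estimated correlation). Targets of PPARγ known from fat and endothelium were lower as a list, with 5 of 20 falling, 0 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.000117 and adjusted p = 0.165 with an estimated correlation). They included the butyrophilin Btnl9 (-0.62 ± 0.09) and Angptl4, an inhibitor of lipoprotein lipase (-0.76 ± 0.15), while the fat-cell target Cidec was at -0.18 (limma adjusted p = 0.195). Angptl4 and Plin2 are on the PPARα list too, and Angptl4 lost the threshold without mixed control 1 (limma adjusted p = 0.0672).

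Genes of lipid synthesis and of the fasting response moved in both directions. Cholesterol synthesis genes were higher as a list, with Msmo1 (1.01 ± 0.19) and Insig1 (0.77 ± 0.14) the 2 of 21 that rose, 6 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000602 and adjusted p = 0.537 with an estimated correlation). The list of fatty acid and triglyceride synthesis did not pass (limma camera adjusted p = 0.921), with 4 of 23 genes higher and 1 lower, 4 higher and 4 lower adjusted over the list alone. Of 19 genes that insulin represses or fasting induces 7 rose and 3 fell, 10 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0428 and adjusted p = 0.362 with an estimated correlation). Igfbp1, the stress-response gene Sesn1 (0.47 ± 0.07) and the coactivator Ppargc1a (0.28 ± 0.05) rose, and Pdk4 and the arrestin Arrdc4 (-0.44 ± 0.07) fell. This last list lost the threshold without Pparg null 1 or mixed control 2 or 3 (limma camera adjusted p up to 0.211). Msmo1 lost it without Pparg null 2 or mixed control 1 (limma adjusted p up to 0.0634) and Insig1 without mixed control 1 (limma adjusted p = 0.0523).

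Genes of the matrix and fibrosis list, which holds contractile genes too, were higher in the Pparg null kidney. Of 32 extracellular matrix and fibrosis genes 11 rose and 0 fell, 18 higher and 0 lower adjusted over the list alone (camera adjusted p = 5.20e-14 and adjusted p = 0.202 with an estimated correlation). The smooth muscle actin Acta2 rose by 0.88 ± 0.11, tenascin C, Tnc, by 0.71 ± 0.11, the contractile protein Tagln by 0.63 ± 0.10 and vimentin, Vim, by 0.48 ± 0.08. Of 12 other smooth muscle genes 3, chosen after their values were seen, rose as well, Cnn1 by 0.74, Tpm2 by 0.50 and Myocd by 0.28, with a median of 0.034 over the 12. Glomerular basement membrane and mesangial genes were higher as a list, with Lamc1 (0.24 ± 0.06) and Col4a2 (0.23 ± 0.06) the 2 of 17 that rose, 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.69e-05 and adjusted p = 0.249 with an estimated correlation). Among 19 podocyte markers Kirrel (0.28 ± 0.05) and Wt1 (0.29 ± 0.06) were 2 of the 3 that rose, 6 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0106 and adjusted p = 0.344 with an estimated correlation). Lamc1 lost the threshold without Pparg null 2 or 3 or mixed control 1, 2 or 3 (limma adjusted p up to 0.0975) and Col4a2 without Pparg null 2 or 3 or mixed control 1, 2 or 3 (limma adjusted p up to 0.153). The podocyte list lost it without mixed control 2 (limma camera adjusted p = 0.0760) and Wt1 without mixed control 1 or 2 (limma adjusted p up to 0.0636).

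Along the nephron some segment lists passed the preset camera test and others did not. Proximal tubule markers were lower as a list, with 4 of 27 falling, 1 higher and 11 lower adjusted over the list alone (camera adjusted p = 2.27e-05 and adjusted p = 0.341 with an estimated correlation). The firmest fall was in Cyp2e1, and the urate transporter Slc22a12 fell by 0.67. The phosphate transporter Slc34a1, chosen after its values were seen, was at -0.01 (limma adjusted p = 0.912). Collecting duct and water transport genes were higher as a list, with 6 of 23 rising, 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000385 and adjusted p = 0.341 with an estimated correlation). The sodium channel subunit Scnn1a (0.35 ± 0.05) and the water channel Aqp2 (0.48 ± 0.10) were among them. The thick limb and distal tubule, intercalated cell and endothelial lists did not pass (limma camera adjusted p = 0.0882, 0.418 and 0.285). Slc22a12 lost the threshold without Pparg null 2 or 3 or mixed control 1 or 3 (limma adjusted p up to 0.0936) and Aqp2 without Pparg null 2 or 3 or mixed control 1 or 3 (limma adjusted p up to 0.0819).

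Injury and cell cycle genes were higher in the same kidneys. Of 24 tubular injury genes 9 rose and 0 fell, 10 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.00e-05 and adjusted p = 0.341 with an estimated correlation). Beside Lcn2 and Krt19 they included S100a6 (0.83 ± 0.13) and Anxa3 (0.53 ± 0.08). Havcr1, which encodes the injury marker KIM-1 and was chosen after its values were seen, was at 0.36 ± 0.35 (limma adjusted p = 0.614). All 33 measured cell cycle genes were above 0, with a median of 0.45, and 7 of them rose, 10 higher and 0 lower adjusted over the list alone (camera adjusted p = 9.25e-12 and adjusted p = 0.344 with an estimated correlation). Cyclin D1, Ccnd1 (0.42 ± 0.06), and the replication helicase subunit Mcm2 (0.57 ± 0.09) rose, as did Mcm6 (0.71 ± 0.16), which lost the threshold without Pparg null 1, 2 or 3 or mixed control 1 or 2 (limma adjusted p up to 0.105).

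Some immune lists passed the preset camera test in the Pparg null kidney and others did not. Neutrophil markers were higher as a list, with 5 of 16 rising and 1 falling, 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000110 and adjusted p = 0.249 with an estimated correlation). The granule proteins Ngp (0.82 ± 0.13) and S100a8 (0.74 ± 0.07) rose, as did Lcn2, which tubular cells also make. Macrophage and dendritic cell markers were higher as a list (camera adjusted p = 0.00231 and adjusted p = 0.639 with an estimated correlation), as were antigen presentation genes (camera adjusted p = 0.0415 and adjusted p = 0.639 with an estimated correlation). By limma 0 of the 27 macrophage and 0 of the 15 antigen presentation genes passed alone, 0 higher and 0 lower adjusted over the list alone for either list, with 4 and 2 at an unadjusted p under 0.05. The macrophage list lost the threshold without Pparg null 1 or mixed control 2 (limma camera adjusted p up to 0.637) and the antigen presentation list without Pparg null 1 or mixed control 2 (limma camera adjusted p up to 0.805), and the class II gene H2-Ab1, chosen after its values were seen, read 11.89, 10.29 and 11.27 on the 3 null arrays. T and NK cell, B cell, interferon and cytokine lists did not pass (limma camera adjusted p = 0.578, 0.456, 0.578 and 0.0503).

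Hormone-linked and clock genes were displaced in the Pparg null kidney. Of 15 glucocorticoid-responsive genes 5 rose and 1 fell, 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.49e-06 and adjusted p = 0.202 with an estimated correlation). The transcription factor Zbtb16 (0.97 ± 0.12) and the chaperone Fkbp5 (0.47 ± 0.10) rose with Lcn2. Clock genes that peak with Bmal1 were higher as a list, with Arntl and Nfil3 the 2 of 4 that rose, 2 higher and 0 lower adjusted over the list alone (camera adjusted p = 3.18e-05 and adjusted p = 0.165 with an estimated correlation). Clock genes that peak opposite were lower as a list, with 5 of 12 falling, 1 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.000294 and adjusted p = 0.341 with an estimated correlation). Beside Dbp the leucine zipper factor Tef fell by 0.39 and Per3 by 0.56. Fkbp5 lost the threshold without Pparg null 2 or mixed control 1 (limma adjusted p up to 0.0661). Tef lost it without Pparg null 2 or 3 or mixed control 1, 2 or 3 (limma adjusted p up to 0.0879) and Per3 without Pparg null 2 or 3 or mixed control 1 or 2 (limma adjusted p up to 0.119).

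Immediate early genes, which respond to handling and dissection, were higher as a list, with Btg2 (0.64 ± 0.08) and Nr4a1 (0.92 ± 0.14) among the 3 of 18 that rose, 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 5.77e-05 and adjusted p = 0.249 with an estimated correlation). Among 26 genes of the NRF2 response 3 fell, Osgin1 by the most (-0.84 ± 0.08), 0 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0108 and adjusted p = 0.307 with an estimated correlation). Unfolded protein and stress response genes were higher as a list, with Sesn2 (0.84 ± 0.21) among the 3 of 24 that rose, 4 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0353 and adjusted p = 0.591 with an estimated correlation). That list lost the threshold without Pparg null 1 or mixed control 1 (limma camera adjusted p up to 0.505) and Sesn2 without any 1 of the 6 arrays (limma adjusted p up to 0.123).

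Lists of other tissues did not pass the camera test in the Pparg null comparison. White fat, brown fat, adrenal, skeletal muscle and red blood cell lists had a limma camera adjusted p of 0.418, 0.187, 0.714, 0.285 and 0.215, while limma fry called the brown fat list lower (adjusted p = 0.0147, median -0.12). The fat lipase Lipe (-0.59 ± 0.09), Pank1 of the brown fat list (-0.43 ± 0.06) and titin, Ttn (-0.31 ± 0.05), fell all the same. Aoc3 of the white fat list (0.38 ± 0.09), the corticotropin receptor Mc2r of the adrenal list (0.42 ± 0.09) and Epb42 of the red blood cell list (0.34 ± 0.09) rose. Aoc3 lost the threshold without Pparg null 2 or 3 or mixed control 1, 2 or 3 (limma adjusted p up to 0.119). Mc2r lost it without Pparg null 2 or mixed control 1, 2 or 3 (limma adjusted p up to 0.0833) and Epb42 without Pparg null 1, 2 or 3 or mixed control 1 or 2 (limma adjusted p up to 0.133). The glucose, oxidative phosphorylation, complement, renin-angiotensin, growth hormone and IGF, calcium and phosphate, nephron progenitor and sex-dimorphic lists had 0.172, 0.961, 0.223, 0.878, 0.235, 0.740, 0.582 and 0.343, and limma fry called the glucose list higher (adjusted p = 0.00725, median 0.014). Of 43 lists 21 passed the preset camera test, 15 up and 6 down, fry passed 16, and with an estimated correlation the count was 0. Some lists past camera failed limma fry, namely collecting duct and fasting (adjusted p = 0.0517 for each), cell cycle (0.0878) and cholesterol synthesis (0.212). Unfolded protein (0.240), macrophage (0.473) and antigen presentation (0.478) lists failed limma fry as well.

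**Figure D1:**
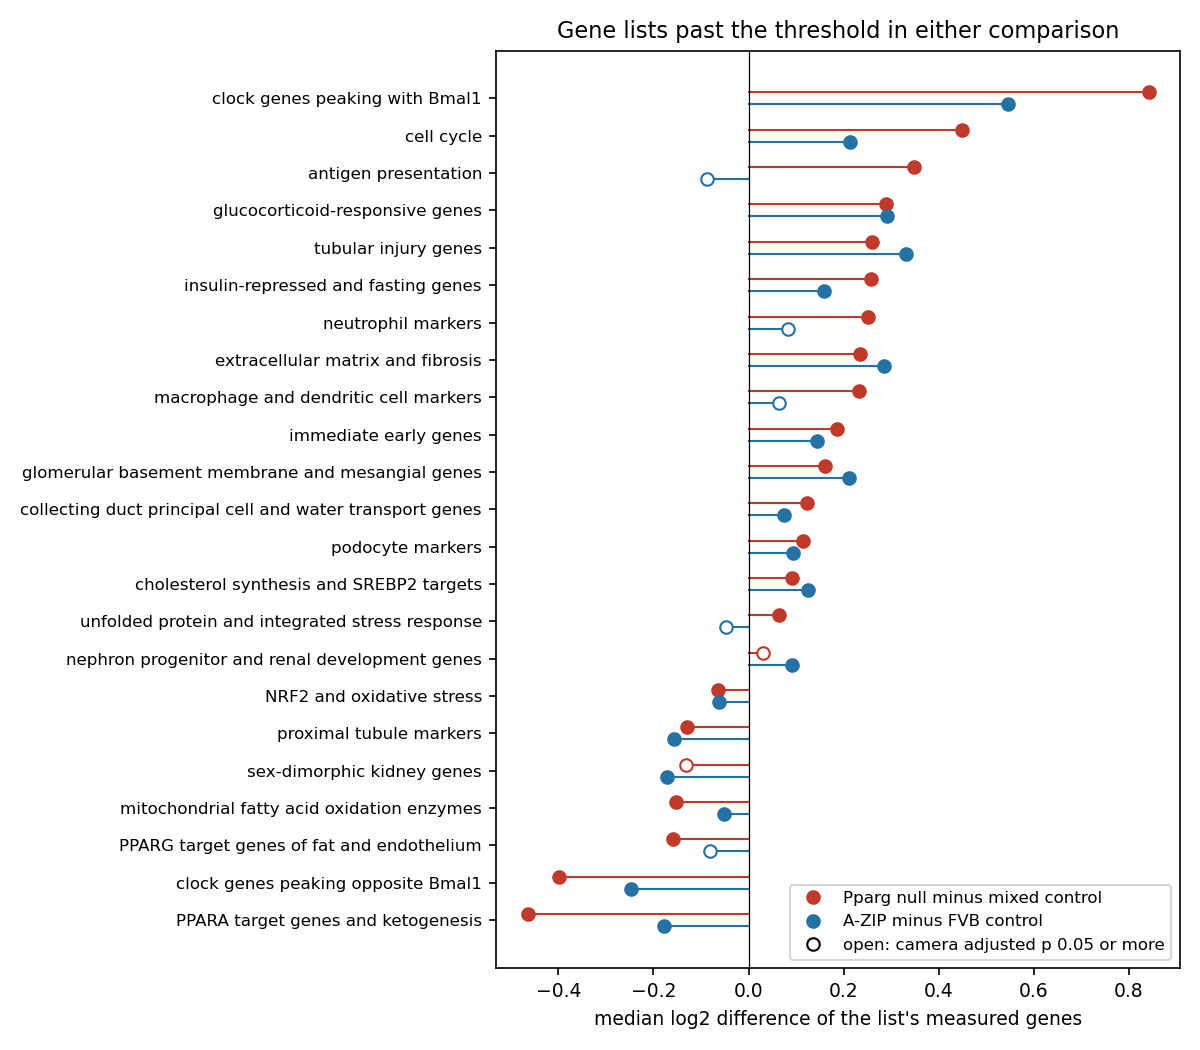
Median log2 difference of each list's measured genes in the Pparg null comparison (red) and the A-ZIP comparison (blue), for lists past the preset camera threshold in at least 1 of them; filled points passed and open points did not. PPARα targets lie at -0.47 and -0.18, matrix and fibrosis genes at 0.24 and 0.29, and 0 lists passed in either comparison when the correlation between genes was estimated.

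The second comparison asked how the kidney differs in mice that lack fat but keep Pparg. A-ZIP kidneys had 485 genes past the threshold, 260 higher and 225 lower than in FVB controls. The largest rises were in Crabp1 (2.15 ± 0.29, 4.45-fold), in Depp1, a gene induced by FoxO factors (1.64 ± 0.28), in Ddit4 (1.54 ± 0.21) and in Etnppl, an enzyme of phosphoethanolamine breakdown (1.36 ± 0.14). The proenkephalin gene Penk rose by 1.29 ± 0.18 and Igfbp1 by 1.26 ± 0.29. The largest falls were in Mfsd2a, a transporter of lysophospholipids (-1.95 ± 0.44), the steroid reductase Akr1d1 (-1.54 ± 0.32), the lipid kinase Pik3c2g (-1.45 ± 0.20) and Slc22a7 (-1.37 ± 0.29). Depp1 lost the threshold without A-ZIP 2 (limma adjusted p = 0.0589). Igfbp1 lost it without A-ZIP 1 or 2 or FVB control 1, 2 or 3 (limma adjusted p up to 0.179) and Mfsd2a without A-ZIP 2 or 3 or FVB control 1 or 2 (limma adjusted p up to 0.172). Akr1d1 lost it without A-ZIP 1, 2 or 3 or FVB control 1 or 2 (limma adjusted p up to 0.112) and Slc22a7 without A-ZIP 2 or FVB control 1, 2 or 3 (limma adjusted p up to 0.130).

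Further large rises in A-ZIP kidneys were in Serpina3n (1.14), the kinase Wnk3 (1.05), Clca3a1 (1.0), Ms4a4a (0.99), Hif3a (0.98) and Tmem100 (0.94). Further large falls were in Ifitm7 (-1.10), the progestin receptor Paqr7 (-1.06), the apolipoprotein Apom (-0.96), the histidine-degrading enzyme Uroc1 (-0.96), the sterol demethylase Cyp51 (-0.95), Eci3 (-0.90), Fcamr (-0.90) and Dnase1 (-0.89). Igfbp1 had the highest adjusted p of these 24 genes, 0.0444 by limma. Hif3a, Tmem100, Paqr7, Apom and Fcamr kept the threshold with each array left out. Wnk3 lost it without FVB control 1 (limma adjusted p = 0.0553). Ms4a4a lost it without FVB control 1 (limma adjusted p = 0.0565), Clca3a1 without A-ZIP 2 or FVB control 1 or 2 (limma adjusted p up to 0.0730) and Eci3 without A-ZIP 2 or FVB control 1 or 2 (limma adjusted p up to 0.0715). Serpina3n lost it without A-ZIP 2 or FVB control 1, 2 or 3 (limma adjusted p up to 0.0941). Dnase1 lost it without A-ZIP 2 or 3 or FVB control 1 or 2 (limma adjusted p up to 0.0770) and Uroc1 without A-ZIP 2 or 3 or FVB control 1 or 2 (limma adjusted p up to 0.155). Ifitm7 lost it without A-ZIP 2 or 3 or FVB control 1, 2 or 3 (limma adjusted p up to 0.135) and Cyp51 without A-ZIP 1, 2 or 3 or FVB control 1 or 2 (limma adjusted p up to 0.164).

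Changes in A-ZIP kidneys had a median size of 0.377, and 81 of the 485 genes changed by at least 1.5-fold and 15 by at least 2-fold. Groups did not overlap in 22.5% of all genes, against 10% by chance. With every array shifted to the same median the count was 529, of which 203 were higher and 326 lower. The count was 62 without FVB control 1, 100 without FVB control 2, 255 without FVB control 3, 122 without A-ZIP 2 and 244 without A-ZIP 3. It was 162 with only these 2 groups in the model, 176 with all probe sets, 785 with a variance trend and 836 with the dimmer genes left out at percentile 50.

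Matrix and fibrosis, basement membrane and injury genes were higher in the A-ZIP kidney. Of 32 matrix and fibrosis genes 9 rose and 0 fell, 19 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.28e-13 and adjusted p = 0.223 with an estimated correlation), among them elastin, Eln (0.49 ± 0.07), and Tnc (0.65 ± 0.11). Col4a1 (0.30 ± 0.05) was the firmest of the 4 basement membrane and mesangial genes, of 17, that rose, 10 higher and 0 lower adjusted over the list alone (camera adjusted p = 4.02e-08 and adjusted p = 0.223 with an estimated correlation). Kirrel (0.30 ± 0.05) was 1 of the 2 podocyte markers, of 19, that rose, 5 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00117 and adjusted p = 0.272 with an estimated correlation). Of 24 tubular injury genes 5 rose, Krt7 (0.38 ± 0.06) among them, 12 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.83e-07 and adjusted p = 0.272 with an estimated correlation). Lcn2 was at 0.87 ± 0.24 with a limma adjusted p of 0.0847. Eln lost the threshold without FVB control 1 (limma adjusted p = 0.0553). Tnc lost it without A-ZIP 2 or FVB control 1 (limma adjusted p up to 0.0770), Col4a1 without A-ZIP 2 or FVB control 1 or 2 (limma adjusted p up to 0.0749) and Krt7 without A-ZIP 2 or FVB control 1 (limma adjusted p up to 0.0592).

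Transport and oxidation genes were lower as lists in A-ZIP kidneys, though few members passed alone. Acsm1 (-0.47 ± 0.07) was the 1 of 27 proximal tubule markers that fell, 0 higher and 8 lower adjusted over the list alone (camera adjusted p = 4.02e-08 and adjusted p = 0.272 with an estimated correlation). Acot4 (-0.54 ± 0.06) was the 1 of 26 PPARα targets that fell, 0 higher and 6 lower adjusted over the list alone (camera adjusted p = 4.02e-08 and adjusted p = 0.272 with an estimated correlation), with Pdk4 at -0.62 and Acot3 at -0.59. Fatty acid oxidation enzymes were lower as a list with 0 of 21 falling by limma, 5 at an unadjusted p under 0.05 and 0 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.00114 and adjusted p = 0.326 with an estimated correlation). Osgin1 (-0.70 ± 0.08) was 1 of the 2 NRF2 genes, of 26, that fell, 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0153 and adjusted p = 0.272 with an estimated correlation). Targets of PPARγ did not pass as a list (limma camera adjusted p = 0.289). The oxidation list lost the threshold without A-ZIP 2 (limma camera adjusted p = 0.0660) and Acsm1 without FVB control 1 (limma adjusted p = 0.0565).

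Glucocorticoid-responsive and fasting genes were higher in the A-ZIP kidney. Zbtb16 (0.84 ± 0.12), Fkbp5 (0.56 ± 0.10), Per1 (0.58 ± 0.10) and Tsc22d3, which encodes GILZ (0.60 ± 0.10), were the 4 of 15 glucocorticoid-responsive genes that rose, 10 higher and 0 lower adjusted over the list alone (camera adjusted p = 4.02e-08 and adjusted p = 0.223 with an estimated correlation). Of 19 insulin-repressed and fasting genes 6 rose and 1 fell, 9 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000566 and adjusted p = 0.223 with an estimated correlation), with Depp1, Igfbp1 and Sesn1 (0.63 ± 0.07) higher. Fkbp5 lost the threshold without FVB control 1 or 2 (limma adjusted p up to 0.0730). Tsc22d3 lost it without FVB control 1 or 2 (limma adjusted p up to 0.0552) and Per1 without A-ZIP 2 or FVB control 1 (limma adjusted p up to 0.0730).

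Clock genes were displaced in A-ZIP kidneys too. Arntl (0.77 ± 0.11) and Nfil3 (0.68 ± 0.11) were the 2 of 4 genes peaking with Bmal1 that rose, 3 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000610 and adjusted p = 0.223 with an estimated correlation). The genes that peak opposite were lower as a list, although Per1, the 1 of 12 that passed, rose by 0.58 ± 0.10, 2 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0450 and adjusted p = 0.606 with an estimated correlation). Dbp was at -0.75 ± 0.19 (limma adjusted p = 0.0595). The opposite list lost the threshold without A-ZIP 1 or 3 or FVB control 2 or 3 (limma camera adjusted p up to 0.154). Nfil3 lost it without FVB control 2 (limma adjusted p = 0.0551) and Per1 without A-ZIP 2 or FVB control 1 (limma adjusted p up to 0.0730).

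Growth and sterol genes were higher as lists in A-ZIP kidneys with few members past the threshold. By limma 0 of 33 cell cycle genes passed, 3 at an unadjusted p under 0.05 and 0 higher and 0 lower adjusted over the list alone (median 0.21, camera adjusted p = 0.000566 and adjusted p = 0.675 with an estimated correlation). The imprinted gene Peg3 (0.43 ± 0.10) was the 1 of 22 nephron progenitor genes that rose, 4 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00269 and adjusted p = 0.223 with an estimated correlation). Among 21 cholesterol synthesis genes Fdft1 (0.33 ± 0.08) rose and Cyp51 (-0.95 ± 0.21) fell, 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00909 and adjusted p = 0.627 with an estimated correlation). Cell cycle genes as a list lost the threshold without A-ZIP 2 or FVB control 2 (limma camera adjusted p up to 0.245) and cholesterol genes without A-ZIP 2 or 3 or FVB control 3 (limma camera adjusted p up to 0.150). Peg3 lost it without A-ZIP 1, 2 or 3 or FVB control 1 or 2 (limma adjusted p up to 0.193). Fdft1 lost it without A-ZIP 2 or 3 or FVB control 1, 2 or 3 (limma adjusted p up to 0.169) and Cyp51 without A-ZIP 1, 2 or 3 or FVB control 1 or 2 (limma adjusted p up to 0.164).

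Btg2 (0.37 ± 0.08) was the 1 of 18 immediate early genes that rose in A-ZIP kidneys, 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00840 and adjusted p = 0.396 with an estimated correlation). Sex-dimorphic genes were lower as a list, with Slc22a7 and Slc7a12 (-0.49 ± 0.12) the 2 of 16 that fell, 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0180 and adjusted p = 0.326 with an estimated correlation). Collecting duct genes were higher as a list with 0 of 23 past the threshold by limma, 7 at an unadjusted p under 0.05 and 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0357 and adjusted p = 0.606 with an estimated correlation). Btg2 lost the threshold without any 1 of the 6 arrays (limma adjusted p up to 0.130). Slc7a12 lost it without A-ZIP 2 or 3 or FVB control 1, 2 or 3 (limma adjusted p up to 0.193) and Slc22a7 without A-ZIP 2 or FVB control 1, 2 or 3 (limma adjusted p up to 0.130). The sex-dimorphic list lost it without A-ZIP 3 (limma camera adjusted p = 0.0768) and the collecting duct list without A-ZIP 3 or FVB control 3 (limma camera adjusted p up to 0.660).

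White fat, brown fat, adrenal, skeletal muscle and red blood cell lists did not pass in A-ZIP kidneys (limma camera adjusted p = 0.170, 0.559, 0.145, 0.593 and 0.0750). Aoc3 of white fat rose by 0.41 ± 0.09 and Slc25a37 of the red blood cell list fell (-0.24 ± 0.05), while Ucp1 of brown fat was at 0.61 ± 0.35 and Chgb of the adrenal at 0.19 ± 0.07 without passing. Aoc3 lost the threshold without A-ZIP 2 or 3 or FVB control 1, 2 or 3 (limma adjusted p up to 0.145) and Slc25a37 without any 1 of the 6 arrays (limma adjusted p up to 0.156). Macrophage, neutrophil, antigen presentation, T and NK cell, B cell, interferon, cytokine and complement lists had 0.559, 0.161, 0.559, 0.662, 0.652, 0.593, 0.0679 and 0.154. Endothelial, intercalated cell, thick limb and distal tubule, renin-angiotensin, growth hormone and IGF, and calcium and phosphate lists had 0.176, 0.366, 0.593, 0.0709, 0.191 and 0.807. Glucose, oxidative phosphorylation, fatty acid and triglyceride synthesis, and unfolded protein lists had 0.0975, 0.707, 0.534 and 0.274, and limma fry called the glucose list higher (adjusted p = 0.0215, median 0.037). Of 43 lists 18 passed the preset camera test, 12 up and 6 down, fry passed 11, and with an estimated correlation the count was 0. Some lists past camera failed limma fry, namely tubular injury (adjusted p = 0.0501), fatty acid oxidation (0.0715), sex-dimorphic (0.0974) and immediate early genes (0.176). Collecting duct (0.302), clock genes opposite Bmal1 (0.356), cholesterol synthesis (0.395) and cell cycle (0.469) lists failed limma fry as well.

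**Figure D2:**
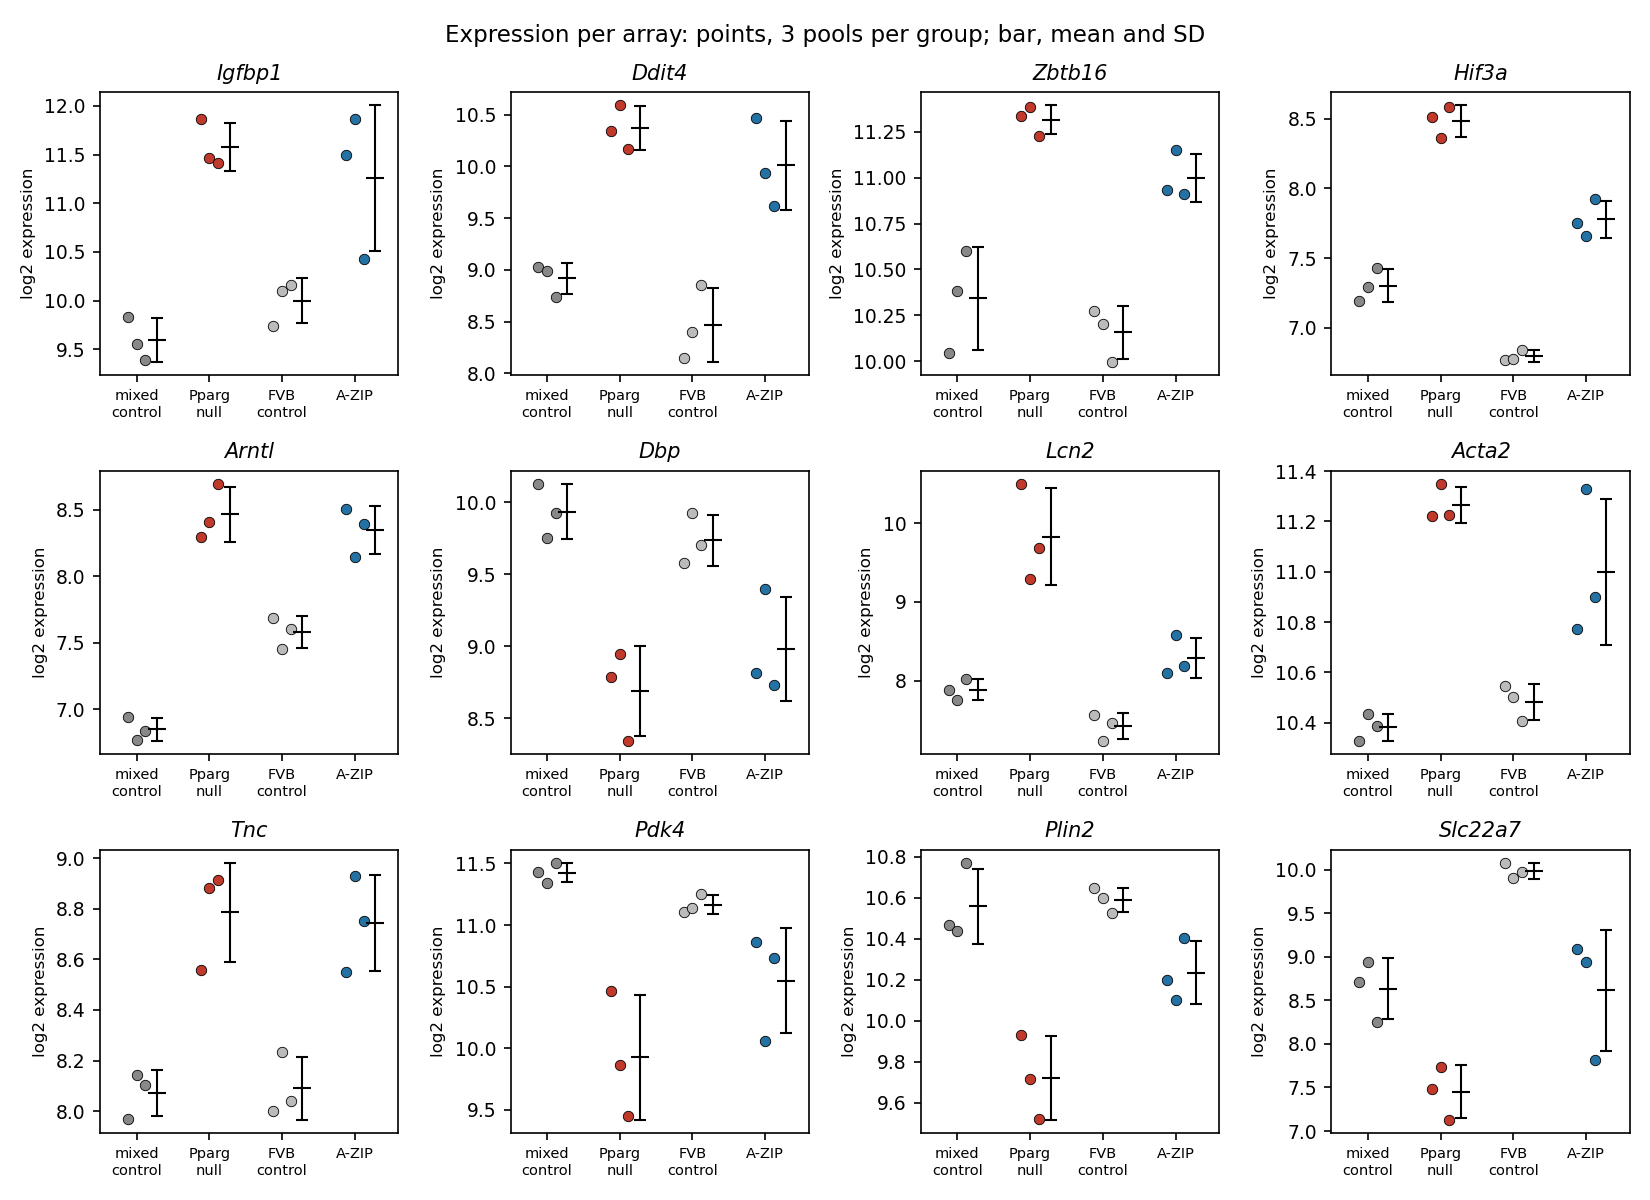
Log2 expression of 12 named genes on each array, with 3 pools per group as points and the group mean with its SD as a bar, on axes that do not start at 0. Zbtb16, Hif3a and Arntl lie above their own controls on all 6 mutant arrays, and Pdk4 fell by 1.5 in Pparg null kidneys against a difference of -0.62 in A-ZIP kidneys.

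Both mutants changed many of the same genes in the same direction. Of the 1055 genes changed in Pparg null and the 485 changed in A-ZIP kidneys 246 were shared, 143 higher in both and 103 lower in both, and 0 changed in opposite directions by limma. Independent lists of these sizes would share 25.7 genes, 6.94 higher and 5.90 lower in both, and 6 and 6.82 in the opposite directions. The odds ratio was 23.7 (Fisher's exact test p = 2.16e-187). Genes are not independent of each other, and both comparisons used the same variance per gene, fitted over all arrays. A gene of low variance is more easily called in both, so these expected counts and this p are not a valid null. Shared variance has no direction, however, and 0 genes were opposite. Models of 2 groups each, which share no variance, had 79 genes in both and 0 opposite. No expected count was made for them. The shared genes with the largest smaller change included Igfbp1 (1.99 in Pparg null and 1.26 in A-ZIP), Ddit4 (1.45 and 1.54), Crabp1 (1.32 and 2.15), Slc22a7 (-1.18 and -1.37), Serpina3n (1.12 and 1.14) and Penk (1.11 and 1.29). Wnk3 (1.15 and 1.05), Ifitm7 (-1.02 and -1.10), Ms4a4a (1.31 and 0.99) and Hif3a (1.18 and 0.98) completed the 10. Arntl, Nfil3, Zbtb16, Fkbp5, Tnc, Acta2, Dnase1, Fcamr, Osgin1 and Acot4 were shared as well. In Pparg null Ifitm7 lost the threshold without Pparg null 1, 2 or 3 or mixed control 1 or 2 (limma adjusted p up to 0.131) and Serpina3n without Pparg null 3 or mixed control 1 or 2 (limma adjusted p up to 0.0604). In A-ZIP Acta2 (0.52 ± 0.11) lost it without A-ZIP 3 or FVB control 1, 2 or 3 (limma adjusted p up to 0.111).

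The same sign was found in A-ZIP kidneys for 94.7% of the genes called in Pparg null kidneys, and in Pparg null for 96.7% of those called in A-ZIP. Across all 19938 genes the 2 sets of differences correlated at r = 0.60 (Spearman's rho 0.485), a description over genes and not over replicates. The 246 shared genes had median sizes of 0.427 in Pparg null and 0.422 in A-ZIP kidneys, but passing in both comparisons selects for similar sizes. Over the genes called in Pparg null, the slope of A-ZIP on Pparg null differences was 0.563, and those were selected in Pparg null alone. Neither value therefore tells how strong 1 response is relative to the other. The shared count was 48 without FVB control 1, 62 without FVB control 2, 135 without FVB control 3, where 1 of them was opposite, and 87 without A-ZIP 2. It was 114, 137 and 158 without mixed control 1, 2 and 3, and 144 and 153 without Pparg null 2 and 3. Models of 2 groups each gave 79, all probe sets 111, a variance trend 410, and genes at or above percentile 25 or 50 379 and 473.

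**Figure D3:**
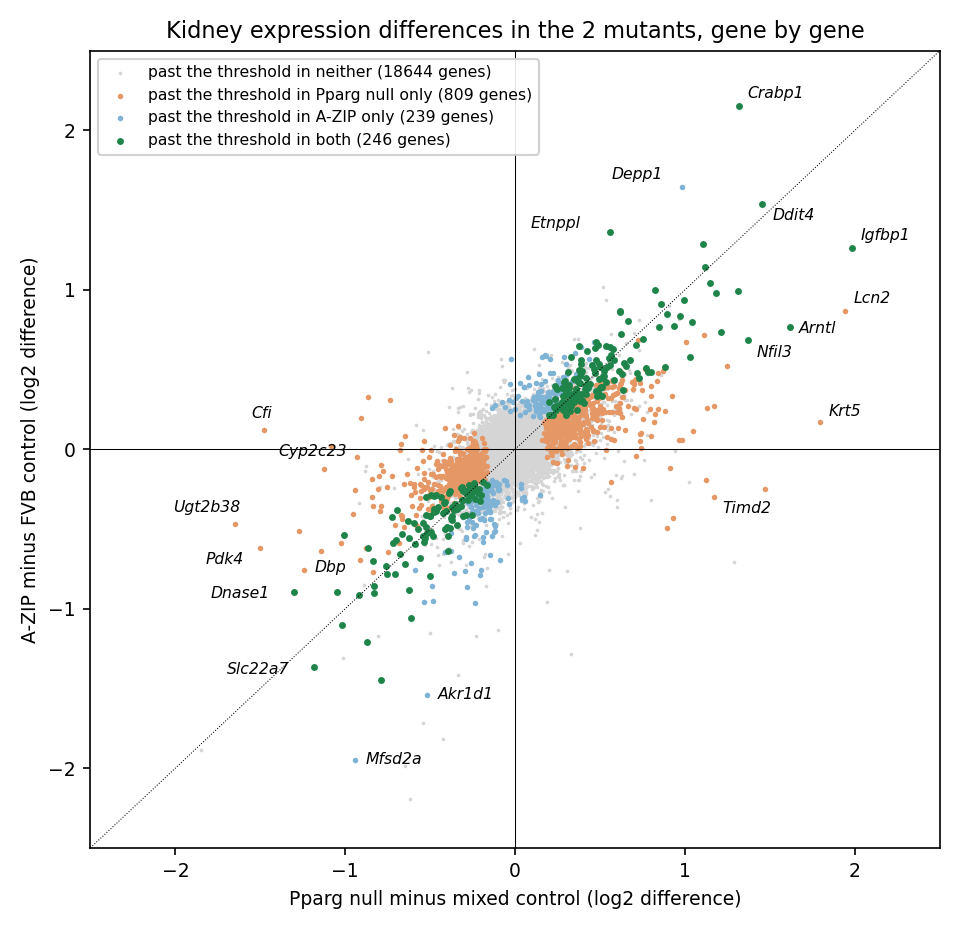
Log2 difference of every gene in A-ZIP kidneys (vertical axis) against that in Pparg null kidneys (horizontal axis), coloured by the comparison in which the gene passed the threshold, with the line of equal differences dotted. The 246 genes past the threshold in both (green) lie in the upper right and lower left quadrants, and Krt5 and Cfi lie near the horizontal axis.

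The third comparison tested the difference of the 2 effects and found 4 genes by limma, against 1160 (5.82%) at an unadjusted p under 0.05. Krt5 rose by 1.80 in Pparg null and was at 0.17 in A-ZIP kidneys, a difference of 1.63 ± 0.20 (limma adjusted p = 0.0215). Actg2, an actin of visceral smooth muscle, rose by 0.91 and was at -0.12, a difference of 1.03 ± 0.11 (limma adjusted p = 0.0206). Cfi fell by 1.48 and was at 0.12, a difference of -1.60 ± 0.20 (limma adjusted p = 0.0215), and the prostaglandin D synthase Ptgds fell by 0.74 and was at 0.31, a difference of -1.05 ± 0.13 (limma adjusted p = 0.0215). Levels of Cfi also differed between backgrounds, with 9.42 ± 0.27 (SD, n = 3) in mixed controls, 7.94 ± 0.11 in Pparg null, 5.59 ± 0.12 in FVB controls and 5.71 ± 0.24 in A-ZIP kidneys. The last 2 lie under the median of every array (7.17 to 7.21), where a fall is hard to read. Of these genes Actg2 lost the threshold without A-ZIP 1 or 2 or FVB control 2 (limma adjusted p up to 0.0625). Krt5 lost it without mixed control 1 or 2, A-ZIP 1, 2 or 3 or FVB control 2 (limma adjusted p up to 0.0915), Cfi without Pparg null 3, mixed control 1, A-ZIP 1 or 2 or FVB control 1, 2 or 3 (limma adjusted p up to 0.0915) and Ptgds without mixed control 1, 2 or 3, A-ZIP 1, 2 or 3 or FVB control 2 (limma adjusted p up to 0.0915). The count was 0 without A-ZIP 1, A-ZIP 2 or FVB control 2, 1 without mixed control 1, 2 without A-ZIP 3 and 9 without Pparg null 2. It was 0 with all probe sets, 1 at percentile 50 and 1 with a replicate block.

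**Figure D4:**
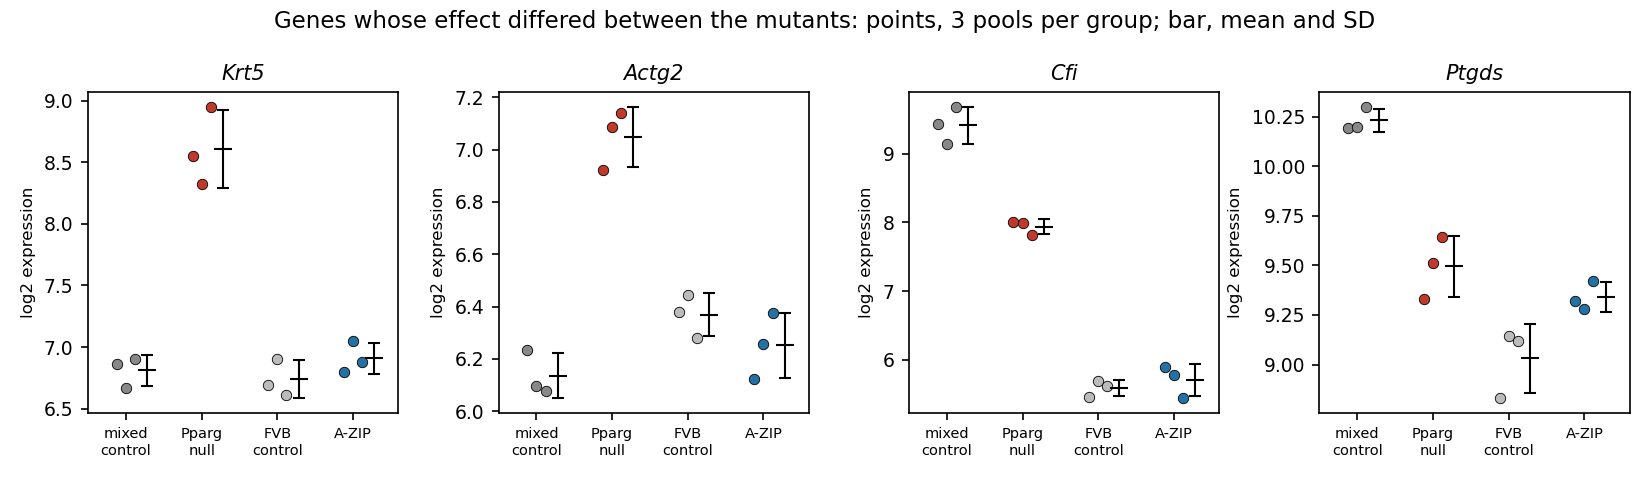
Log2 expression on each array of the 4 genes whose effects differed between the mutants, with 3 pools per group as points and the group mean with its SD as a bar, on axes that do not start at 0. Krt5 averaged 8.61 in Pparg null kidneys against 6.81, 6.91 and 6.74 in mixed control, A-ZIP and FVB control kidneys.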

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

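In this part the splits, the PPARα and clock tests and the SD between superficial genes were chosen after the results were seen, the 2 urothelial tests after those of Krt5, Actg2 and Upk1b but before the values of their own genes were looked at, and the gene and list tests of the difference and the probe sets with no single symbol were planned beforehand.

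Krt5 and Actg2 were higher in Pparg null kidneys and not in A-ZIP kidneys (differences of 1.63 and 1.03), while the uroplakin Upk1b, chosen after its values were seen, fell by 0.91. More renal pelvis in the Pparg null pools could raise such genes and the superficial ones by about as much, but 12 superficial urothelial genes scored -0.0179 ± 0.08 (log2 difference with SE). Their median of -0.096, with an SD between genes of 0.33, lay below the rises of Krt5 (1.80) and Actg2 (0.91) by more than that SD. Those 2 genes were picked for their large effects, and the 17 basal urothelial genes had a median of only 0.166. Most of the 17 averaged under the median of every array (7.17 to 7.21), where a change is hard to read. Krt6b (4.22), Dsg3 (4.66) and Krt6a (5.12) were far under it. The comparison with the superficial genes therefore cannot decide whether more renal pelvis was the cause. As a set, the superficial genes did not rise with the basal ones, which scored 0.23 ± 0.05 in Pparg null. A candidate explanation is a basal shift of the urothelium that A-ZIP lacks. The basal minus superficial score was 0.25 ± 0.07 in Pparg null and -0.09 ± 0.07 in A-ZIP, a difference of 0.33 ± 0.10. Part of it came from the superficial genes in A-ZIP (0.15 ± 0.08), and the basal score alone differed by 0.16 ± 0.07. An effect on smooth muscle was not tested apart from it (12 genes, 3 higher, median 0.034). Their score was 0.13 ± 0.06 in Pparg null and 0.10 ± 0.08 in the difference of the effects. By limma 3 of 17 basal genes rose (Krt14 by 0.97, Krt15 by 0.71 and Krt6a by 0.32) and 0 fell, while the superficial genes went both ways, with 5 of 12 above 0, Gprc5a higher by 0.58 (0.63 in A-ZIP) and Grhl3 lower (-0.18).

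PPARα targets had a median of -0.47 in Pparg null kidneys (limma camera adjusted p = 2.58e-17, adjusted p = 0.165 with an estimated correlation) and a median difference of the 2 effects of -0.23 (limma camera adjusted p = 1.09e-06, adjusted p = 0.333 with an estimated correlation and 0.240 by fry). A lower share of proximal tubule cells could lower them. The targets scored lower than proximal tubule markers by 0.29 ± 0.06 in Pparg null and by 0.26 ± 0.09 in the difference of the effects. They fell further there than a share that lowered both alike would give. In A-ZIP this gap was 0.0384 ± 0.06 and such a share stays open. Other cell-type lists had medians in Pparg null of 0.059 (thick limb), 0.024 (endothelium), -0.017 (intercalated cells), 0.11 (podocytes), 0.12 (collecting duct), 0.25 (neutrophils), 0.23 (macrophages), -0.024 (T and NK cells) and -0.066 (B cells). Fat carried along in the mixed control pools could also lower the targets. In Pparg null they scored lower than white fat genes by 0.40 ± 0.10 and than brown fat genes by 0.32 ± 0.11. In the difference of the effects these were 0.0935 ± 0.14 and 0.0236 ± 0.15, and fat stays open there. Both comparisons were chosen when the list medians were known, and the targets had the lowest of these in Pparg null. Their larger fall was thus known beforehand, and the gaps give its size without testing either cause. Loss of Pparg in kidney cells and the lack of fat in the body both stay open.

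Clock genes had a median difference of the 2 effects of 0.35 for those peaking with Bmal1 and -0.24 for those opposite, which passed limma camera at the preset correlation, with adjusted p = 0.325 and 0.622 with an estimated correlation and 0.209 and 0.594 by fry. Collection of the mutants at another time of day could move Arntl, Nfil3 and Dbp, and 27 of 32 clock results had the sign that 1 shift of phase gives. Times of day are not in the labels used here, so this cannot be told from an effect of the mutations. Per1, which glucocorticoids also raise, was the 1 called result of the other sign. The list opposite Bmal1 lost the threshold without Pparg null 3, mixed control 1, A-ZIP 2 or FVB control 1 (limma camera adjusted p up to 0.367).

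The splits of arrays into groups of the same sizes tell little for single comparisons. With 10 splits, 1 gave as many genes as the real one in Pparg null (1055, highest other 0) and 1 in A-ZIP (485, highest other 0), and the splits are too few. The same holds for lists, with 1 of 10 in Pparg null (21, highest other 19) and 1 of 10 in A-ZIP (18, highest other 17). For the difference of effects 7 of 100 splits gave as many genes (4, highest other 40) and 35 of 100 as many lists (14, highest other 22). The 6 other splits with as many genes, that of 40 included, all kept the real grouping of the Pparg null comparison and carry its effect, so these counts do not tell whether chance gave the 4 genes. Of 79 splits that kept neither grouping 17 gave as many lists (highest 19), so for lists chance is not excluded. As many genes came from 0 of the 79. Such splits mix mutant with control arrays, which widens the spread within groups, so this 0 does not exclude chance for the 4 genes either. For shared genes 1 of 100 splits, the real one, gave 246 (highest other 0), but each other split of either comparison called 0 genes, so this count adds nothing to the splits of the single comparisons and does not exclude chance.

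Cfi and Ptgds differed between the effects by -1.60 and -1.05, with Cfi in FVB controls and A-ZIP at 5.59 and 5.71, under the median of every array. The median differences of the 2 effects were -0.098 for white fat, -0.17 for brown fat, -0.16 for PPARγ targets and -0.086 for fatty acid oxidation. They were 0.12 for macrophages, 0.22 for neutrophils, 0.43 for antigen presentation and 0.23 for the cell cycle. They were -0.086 for nephron progenitors, 0.13 for unfolded protein genes and 0.25 for red blood cells. The 14 lists, clock and PPARα lists included, passed camera at the preset correlation, and 0 passed with an estimated correlation or with fry. White fat lost the threshold without FVB control 1 (limma camera adjusted p = 0.0699), brown fat without mixed control 1 or 3 (limma camera adjusted p up to 0.0878) and fatty acid oxidation without mixed control 1 or A-ZIP 1 (limma camera adjusted p up to 0.202). Macrophages lost it without Pparg null 1, mixed control 2 or A-ZIP 1 or 3 (limma camera adjusted p up to 0.988) and antigen presentation without Pparg null 1 or mixed control 2 (limma camera adjusted p up to 0.834). Cell cycle lost it without mixed control 2 or A-ZIP 3 (limma camera adjusted p up to 0.134) and progenitors without mixed control 2 (limma camera adjusted p = 0.0619). Among 13767 probe sets with no single gene symbol 159 passed in Pparg null (107 higher) and 15 in A-ZIP (10 higher).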

How the results depend on the processing

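All alternatives here were chosen before the results were seen. Igfbp1, Lcn2, Krt5 and the other genes named by the rule gave 170 calls, of which 68 held under all settings tried, 102 were lost under at least 1 and 0 reversed. With only the groups compared 607 genes passed in Pparg null, 162 in A-ZIP and 79 in both. An adjusted p under 0.10 gave 1938, 1035, 7 for the difference and 551 in both, and a fold of at least 1.5 gave 181, 81 and 45 in both. These 2 thresholds change the counts by construction. All probe sets gave 176 in A-ZIP, 0 for the difference (limma, 1160 genes at an unadjusted p under 0.05 in the gene table) and 111 in both. A variance trend gave 785 in A-ZIP and 410 in both. Genes at or above percentile 50 gave 836 in A-ZIP, 1 for the difference and 473 in both, and percentile 25 gave 379 in both. Leaving an array out, or using only the groups compared, also leaves fewer arrays for the estimates, which by itself lowers power. How much of the loss this made, and the cause for the other settings, was not tested. Camera with an estimated correlation called 0, 0 and 0 lists, and fry 11 in A-ZIP and 0 for the difference. With 1 array left out the counts ran from 330 to 1084 in Pparg null, 62 to 569 in A-ZIP, 0 to 9 for the difference and 48 to 314 in both, and lists from 17 to 25, 15 to 19 and 12 to 17. The adjusted p of the antigen presentation list in Pparg null ran from 4.36e-07 to 0.805, where its direction turned without Pparg null 1. Uncalled genes near 0 changed sign: Kdm5d from -0.0853 to 0.0925 and Uty from -0.115 to 0.0587 in Pparg null, Kdm5d from -0.0176 to 0.0793 and Clock from -0.0187 to 0.0516 in A-ZIP, with Clock at -0.0088 after the shift to equal medians. Robust variance was not run for lists, since camera has no such option.

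With the replicate number as a replicate block 1102 genes passed in Pparg null, 694 in A-ZIP, 1 for the difference and 358 in both, 1 of them opposite. Arrays of the same number correlated in their deviations from the group mean at 0.184, 0.179 and 0.009 in the Pparg null comparison. In A-ZIP these were -0.036, -0.103 and -0.010. Mixed with FVB controls gave 0.247, 0.181 and 0.135, against -0.157 to 0.005 for unequal numbers. Pparg null with FVB controls gave 0.126, 0.068 and 0.132. A-ZIP gave 0.146, -0.21 and 0.034 with mixed controls and 0.006, -0.084 and 0.228 with Pparg null. The numbers are not stated to pair pools and were not read as pairs, but an effect common to arrays of the same number is not excluded.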

Other observations

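The flanking DNA test in this part was chosen before the positions of the called genes were looked at, and the genes below, apart from Ucp1 and Xist, were chosen after their values were seen.

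Some genes of lipid and glucose use rose in 1 or both mutants. The desaturase Scd2 rose by 0.77 in Pparg null and 0.51 in A-ZIP kidneys, while its relative Scd1 was at -1.01 and -1.31 (limma adjusted p = 0.117 and 0.0723). The phosphatidate phosphatase Lpin1 rose by 0.62 and 0.86, and the glucose transporter Slc2a1 by 0.36 and 0.25. Hexokinase 2, Hk2, rose by 0.39 in Pparg null kidneys and was at 0.09 in A-ZIP. The fatty acid and triglyceride synthesis and glucose lists did not pass limma camera in Pparg null (adjusted p = 0.921 and 0.172) or A-ZIP (0.534 and 0.0975). In Pparg null 4 genes of each list were higher, with 1 and 2 lower, and fry called the glucose list higher in both mutants.

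Single arrays stood out for some genes. Cd74 read 11.93, 10.09 and 11.01 and Psmb8 9.80, 7.16 and 7.88 on the 3 Pparg null arrays, and Ucp1 read 6.43, 7.39 and 5.44 on the 3 A-ZIP arrays. Xist averaged 12.22, 12.29, 12.23 and 12.23 in the 4 groups.

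DNA of another strain around the targeted Pparg locus could bring its own expression differences. Within 20 Mb of Pparg on chromosome 6, 13 of 342 genes (3.8%) were called in Pparg null kidneys, against 1039 of 19513 elsewhere (5.32%). The odds ratio was 0.703 (95% interval 0.369 to 1.22, Fisher's exact test p = 0.271), which argues against an excess of such genes at that distance. Strain differences elsewhere in the mixed background stay open.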
